A study of Mus musculus with 23 samples.

How the data were processed

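RNA of mouse colon was measured on 23 Affymetrix mouse genome arrays, 1 per animal. C57BL/6J is a common inbred laboratory strain. The mice received 3% dextran sulfate sodium (DSS), a sulfated polysaccharide that injures the colon epithelium, in their drinking water. Per the labels, separate cohorts gave colon before treatment (day 0) and after 2, 4 or 6 days, so the 5 arrays of day 0 and the 6 arrays of each later day are different animals. Arrays are named here by day and mouse number, such as day 2 mouse 8. The piece of colon and the hour at which it was taken are not given in the sources used here.

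The deposited values are the authors' signal intensity per probe set on a linear scale. Per the submitters' processing notes they were made with MAS5, of which no version is given. In the values, the mean after trimming 2% at each end was 500 on each array (the highest over the lowest was 1.0). Medians over the probe sets other than controls lay between 97.3 and 121. No pair of arrays held mostly identical values. Because the scaling by the authors already matched the trimmed means, no further normalization was applied. Such scaling sets the mean of all arrays alike and cannot show a change in total RNA per cell. The number of arrays limits the precision of each value.

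Of 45101 probe sets, 64 were controls, and these were left out of the tests. The platform annotation, which could be old, gave 1 gene symbol for 34957 probe sets, several for 920 and none for 9160. Only probe sets with 1 symbol were named. A probe set was kept if at least 5 arrays lay above the median (50th percentile) of their own array. This left 24627 probe sets, 21641 of them with 1 symbol, for 12464 genes. For the 5547 genes with more than 1 kept probe set, the probe set with the highest mean was used. Signals were analysed as log2(signal + 16). A fold change on that scale understates changes of dim genes. It compares means of log levels, so it can differ from the ratio of the mean signals where the arrays of a day spread widely.

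Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend). All 4 days were in 1 fit, so that they shared an estimate of the spread. Each of 5 contrasts was adjusted by the Benjamini-Hochberg method, and a gene passed at an adjusted p of 0.05 or less. All tests were two-sided. A count of genes without overlap is of those whose arrays of 1 day all lay above or all below those of the other. On simulated data for the day 0 to day 6 comparison (12464 genes), the fit recovered 52.2% of genes changed by 0.5 on the log2 scale, 88.1% of those changed by 1 and 97.0% of those changed by 2. In that simulation 8 of 178 genes called were unchanged. Its noise was independent between genes and few genes were changed, so these rates need not hold for the real arrays.

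Lists of genes for pathways, cell types and tissues that can be dissected with the colon were fixed together with the tests, the filter, the main settings and most alternatives before the data were examined. They are 38 lists with 881 entries, of which 803 matched the annotation. At least 3 measured members were needed for a test, which 37 lists had. Markers of red blood cells had too few and were not analysed here. A list was tested with limma's camera, which asks whether its members moved relative to the other genes, with a correlation between genes of 0.01. The p-values were adjusted over the 37 lists within a contrast. Another 4 lists, of clock genes peaking with Dbp or with Arntl, pan-epithelial genes and posterior Hox genes, were made after the data were seen and adjusted among themselves. The same test with an estimated correlation, and limma's fry, were alternatives. Members that passed were counted over all genes tested and, separately, adjusted over the list alone. The error given with a mean over a list is the SD between its members.

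Named genes followed a rule. For each comparison with day 0 it took the 8 largest increases and 8 largest decreases among genes that passed without overlap between the days, and 5 of each for day 2 to day 4 and day 4 to day 6. From each list and comparison it took up to 3 members that passed with the largest change, or up to 2 with the lowest p where none passed. Genes taken in 1 comparison may be given in others. The rule took 285 genes. The text gives 107 of them, a choice made after their values were seen. A few other genes, marked as chosen after their values were seen, stand outside the rule.

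The ratio of 3' to 5' control probe sets of beta-actin and Gapdh was compared with day 0 by an exact permutation test, adjusted over 12 tests that included the hybridization controls (bacterial and phage transcripts added to each sample) and 18S rRNA. Comparisons with day 0 share its 5 arrays. Their overlap was therefore set beside 100 simulations of unchanged groups, beside the overlap of independent lists, and beside 20 splits of day 0 into 2 and 3 arrays. Alternatives fixed in advance were pseudocounts of 1 and 64, no filter, a filter at the 75th percentile, quantile normalization, centring on array medians, no mean-variance trend, only the days compared in the fit, a mouse number block, mice numbered 1 to 8 alone, the mean of a gene's probe sets, leaving out probe sets prone to cross-hybridization, array weights, and leaving out each array in turn. Chosen after seeing the data were fits without arrays that carried pancreatic RNA or little squamous and skeletal muscle RNA, and fits with the squamous marker level, the skeletal muscle marker level or the hybridization control level as a covariate.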

Results

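Colon from mice given 3% DSS in drinking water, a standard model of acute colitis, was profiled over the first 6 days of exposure, with 5 animals at day 0 and 6 each at days 2, 4 and 6. The comparisons ask which transcripts differ from untreated colon at each day and which differ between successive days. Values are signal intensities from 23 arrays scaled by the authors to a common trimmed mean, and 12464 genes were tested.

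Arrays carried RNA of neighbouring tissue. Squamous and skeletal muscle RNA was present on most, with Krt10 from 2537 to 16710 and Acta1 from 1516 to 17400 on the 19 arrays other than those named below. Pancreatic RNA stood out on few. On day 2 mouse 6 the pancreatic enzyme genes Prss2 and Clps, chosen after their values were seen, had signals of 28000 and 25970, against medians of 113 and 877 on 19 other arrays. Day 6 mouse 1 had 9692 and 4605. The squamous keratin genes Krt10 and Krt1 had medians of 7102 and 3272 on those 19 arrays, but 306 and 43.7 on day 2 mouse 8 and 350 and 46.5 on day 4 mouse 8. The skeletal muscle gene Acta1 was also low on both, at 474 and 351, against a median of 7540. All these genes were picked after their values were seen.

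**Figure D1:**
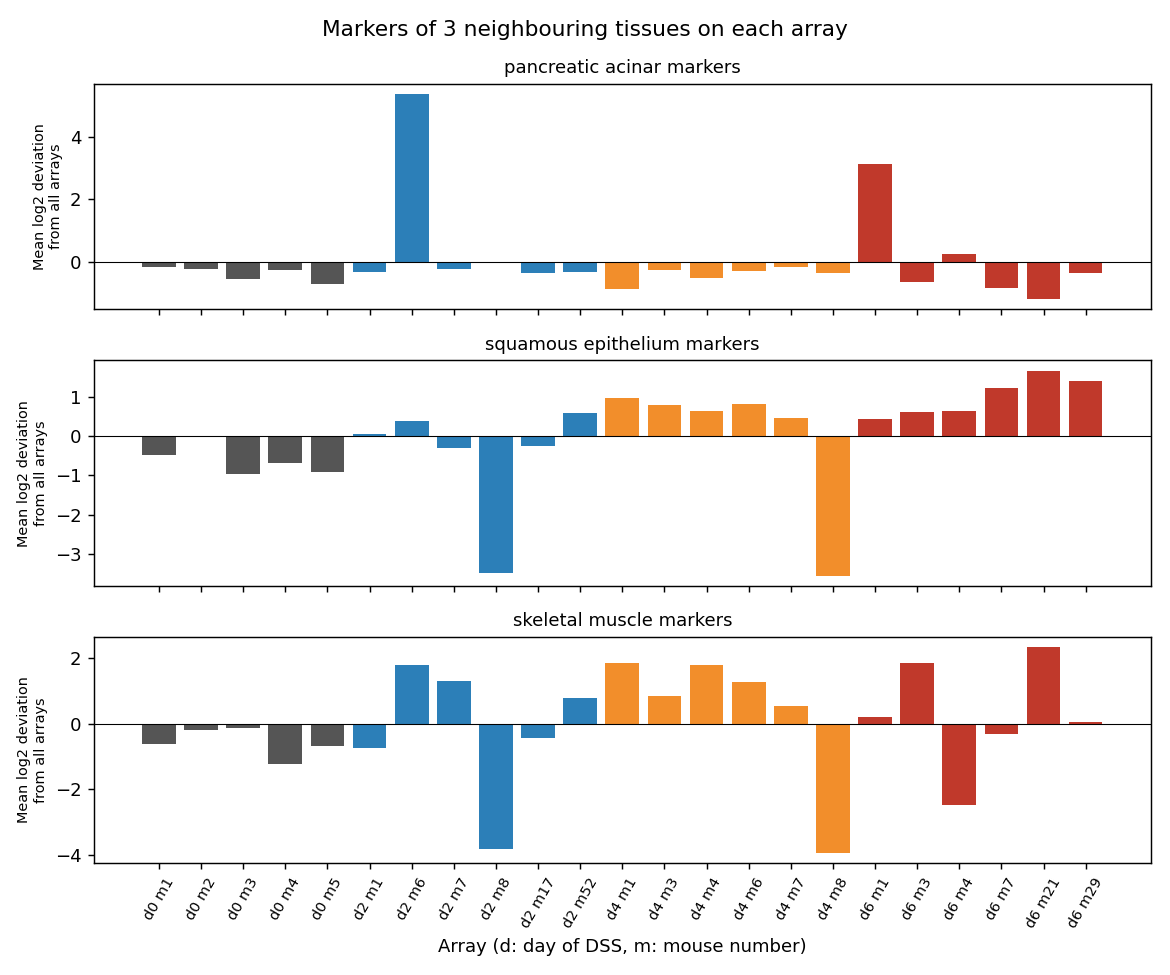
Mean log2 level of the pancreatic acinar, squamous epithelium and skeletal muscle marker lists on each of the 23 arrays, as the deviation from the mean of all arrays, with 1 bar per array grouped by day. The pancreatic markers stand highest on day 2 mouse 6 and day 6 mouse 1, and the squamous markers lowest on day 2 mouse 8 and day 4 mouse 8.

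RNA quality measures moved with day. The 3' to 5' log2 ratio of beta-actin rose from 0.43 ± 0.02 (SD, n = 5) at day 0 to 0.61 ± 0.06 (SD, n = 6) at day 4 and 0.51 ± 0.04 (SD, n = 6) at day 6 (exact permutation p = 0.00433 and 0.00216, adjusted p = 0.00866 and 0.00648). For Gapdh the ratio rose by 0.18 at day 4 and 0.15 at day 6 (exact p = 0.00216 for both, adjusted p = 0.00648). At day 2 the differences were 0.03 for beta-actin (exact p = 0.264, adjusted p = 0.317) and 0.05 for Gapdh (exact p = 0.173, adjusted p = 0.231). The hybridization controls fell by 0.37 at day 4 (exact p = 0.00216, adjusted p = 0.00648) and fell by 0.50 at day 6 (exact p = 0.00433, adjusted p = 0.00866) on the log2 scale. Every array of days 4 and 6 lay at or under 11.39, below the lowest day 0 array at 11.55. No hybridization batch is given in the sources used here, and a batch that followed day could not be separated from day in comparisons of days 4 and 6 with day 0 or of day 4 with day 2. At day 2 they differed by -0.05 (exact p = 0.476, adjusted p = 0.519). The 18S rRNA control differed by 0.13 at day 2 (exact p = 0.591, adjusted p = 0.591), 0.67 at day 4 (exact p = 0.0714, adjusted p = 0.122) and 0.48 at day 6 (exact p = 0.0866, adjusted p = 0.13).

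After 2 days of DSS few genes differed from untreated colon. Axin2, a Wnt target and inhibitor, fell to 0.489 of its day 0 level (log2 change -1.03 ± 0.15, SE), from a mean signal of 770.2 ± 78.6 (SD, n = 5) to 374 ± 81.6 (SD, n = 6), with adjusted p = 0.00571. Jchain, which links immunoglobulin units in plasma cells, fell from 8560 ± 1372 to 4686 ± 843 (log2 change -0.87 ± 0.16, adjusted p = 0.0298). Dbp, a transcription factor under circadian control, rose 3.73-fold (log2 change 1.90 ± 0.37, adjusted p = 0.0428), and the keratin gene Krt7 rose 1.48-fold (0.57 ± 0.09, adjusted p = 0.00726). The other genes that fell were Cpm (log2 change -1.06 ± 0.20), Lonrf3 (-0.79 ± 0.13), Clock (-0.49 ± 0.09), a core gene of the circadian clock, Sike1 (-0.48 ± 0.07), Fbxo33 (-0.43 ± 0.08) and Ube2s (-0.40 ± 0.08). In all, 2 genes rose and 8 fell, while 1594 had an unadjusted p below 0.05. Values of 283 genes did not overlap between the days, where chance gives 0.433% of the genes. Quantile normalization gave 4 higher and 8 lower, and median centring 4 and 6.

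Each of the 10 calls at day 2 was lost under at least 1 setting fixed in advance, such as Krt7 with mice numbered 1 to 8 alone (adjusted p = 0.0681) and Lonrf3 with the mean of its probe sets (adjusted p = 0.0514). Settings other than the mouse number block and leaving out single arrays ended 8 of them. The calls of 6 genes ended when a single array was left out. Leaving out any of 14 arrays ended the call for Dbp, any of 13 for Fbxo33 and Ube2s, any of 8 for Cpm and any of 7 for Jchain and Clock. The highest adjusted p was 0.13 for Dbp, 0.126 for Cpm and Fbxo33 and 0.129 for Ube2s, each without day 0 mouse 2, 0.0878 for Jchain without day 2 mouse 6 and 0.0767 for Clock without day 0 mouse 3. Leaving out day 0 mouse 4 gave 9 higher and 23 lower, day 6 mouse 1 gave 4 and 8, and day 6 mouse 21 gave 6 and 12. The counts were 1 and 3 without day 0 mouse 1, day 0 mouse 2 or day 2 mouse 17, 1 and 4 without day 0 mouse 3 or day 2 mouse 8, 1 and 5 without day 0 mouse 5 or day 2 mouse 6, and 2 and 5 without day 2 mouse 7. They were 1 and 10 without day 2 mouse 52, 1 and 6 without day 4 mouse 1, 1 and 7 without day 4 mouse 7, and 1 and 8 without day 6 mouse 4.

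Cell cycle and crypt genes leaned lower at day 2. The 34 measured genes of cell cycle and DNA replication had a mean log2 change of -0.37 ± 0.33 (SD of members, camera adjusted p = 5.68e-12), with 0 passing over all genes and 1 higher and 16 lower adjusted over the list alone. Top2a, a topoisomerase of dividing cells, had a log2 change of -0.74 (adjusted p = 0.0665). Among 16 stem and crypt base markers the mean was -0.34 ± 0.41 (adjusted p = 2.75e-06), with 0 higher, 1 lower, Axin2, and 8 lower adjusted over the list alone. The B cell and plasma cell list (16 members) shifted by -0.37 ± 0.25 (adjusted p = 0.000669), with 0 higher, 1 lower, Jchain, and 2 lower adjusted over the list alone. With an estimated correlation adjusted p = 0.644 for the cell cycle and B cell lists and adjusted p = 0.14 for the stem cell list.

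In 8 lists day 2 values leaned higher, though 0 members passed over all genes. The acute phase list (13 members, mean 0.43 ± 0.47, adjusted p = 0.00111) had 3 higher adjusted over the list alone, and its member Serpina3n, a protease inhibitor, had a log2 change of 1.23 (adjusted p = 0.103). Endothelial markers (22, mean 0.28 ± 0.18, adjusted p = 7.57e-05) had 2 higher and enteroendocrine markers (18, mean 0.25 ± 0.21, adjusted p = 0.000447) 1 higher adjusted over the list alone. Gcg, the gene of glucagon-like peptides, had a log2 change of 0.62 (adjusted p = 0.0619). The lists of enteric neurons and glia (18, mean 0.23 ± 0.35, adjusted p = 0.0196, 1 higher adjusted over the list alone), fatty acid oxidation (26, mean 0.09 ± 0.21, adjusted p = 0.00449, 2 higher adjusted over the list alone), smooth muscle (17, mean 0.19 ± 0.14, adjusted p = 0.000207), glycolysis (24, mean 0.14 ± 0.16, adjusted p = 0.014) and mitochondrial respiration (36, mean 0.04 ± 0.04, adjusted p = 0.0253) shifted less, the last 3 with 0 adjusted over the list alone. With an estimated correlation adjusted p = 0.184 for the enteroendocrine list and adjusted p = 0.644 for the other 7. Some calls ended when a single array was left out, with adjusted p = 0.0657 for neurons and glia without day 0 mouse 5, 0.169 for mitochondrial respiration without day 0 mouse 1, the highest of 4 arrays that ended it, and 0.12 for glycolysis without day 2 mouse 6. Without day 2 mouse 8, 17 lists passed, against 11 with all arrays. Another 26 lists did not pass, with means between -0.32 and 1.07 and a lowest adjusted p of 0.0871. Mean, median and test differed in sign for extracellular matrix, junction and MHC class II genes.

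At day 4, matrix proteases and stromal genes were higher than in untreated colon, as were Il6 and Cxcl9. Mmp3, which degrades matrix proteins, rose 5.25-fold from a mean signal of 88.8 ± 28.4 (SD, n = 5) to 565 ± 233 (SD, n = 6), with a log2 change of 2.39 ± 0.27 (SE, adjusted p = 1.41e-05). Il6, an inflammatory cytokine, rose 4.1-fold (log2 change 2.04 ± 0.32, adjusted p = 0.000329, log2 change 3.56 with a pseudocount of 1 and 1.04 with 64) and the T cell chemokine gene Cxcl9 4.13-fold (2.05 ± 0.44, adjusted p = 0.00312). Hbegf, an epidermal growth factor receptor ligand, fell to 0.238 of day 0 (log2 change -2.07 ± 0.38, adjusted p = 0.000985), and Ppargc1a, a coactivator of mitochondrial biogenesis, to 0.36 (-1.48 ± 0.29, adjusted p = 0.00156). With the mean of its probe sets the change of Ppargc1a was -0.36 (adjusted p = 0.299).

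The other large increases at day 4 were in Mmp10 (log2 change 1.97), Calhm6 (1.86), the acute phase gene Saa3 (1.83), Upk3b (1.75) and the hyaluronan-binding Cemip (1.71). Large decreases were in Gprin3 (-1.93), 2310079G19Rik (-1.65), the insulin receptor substrate gene Irs2 (-1.64), Cpn1 (-1.54), Cpm (-1.50) and Bnip5 (-1.39). In total 1504 genes rose and 539 fell (limma), 77 and 37 of them at least 2-fold, and 1253 genes did not overlap, with chance at 0.433%. Averaging the probe sets of each gene gave 1201 higher and 952 lower. It kept 1446 of the 2043 calls and turned the sign of 133. With the hybridization control level, which moved with day, as a covariate, 264 were higher and 68 lower, and 29 of 41 named calls were lost.

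Vascular, neural and stromal markers rose at day 4. Of 22 endothelial markers 18 rose and 0 fell (mean log2 change 0.67 ± 0.28, camera adjusted p = 7.23e-09), 20 adjusted over the list alone. They included Sox17, a transcription factor of arterial endothelium, which rose 2.58-fold (log2 change 1.37 ± 0.20, adjusted p = 0.000219), and Mmrn2 (1.15 ± 0.16). Among 18 markers of enteric neurons and glia 13 rose and 0 fell (mean 0.65 ± 0.30, adjusted p = 7.4e-08), 15 adjusted over the list alone. Members included Stmn2 at 0.96 ± 0.14. In the extracellular matrix and fibroblast list 16 of 23 rose and 0 fell (mean 0.48 ± 0.18, adjusted p = 8.96e-09), 18 adjusted over the list alone, among them the proteoglycan gene Lum (0.87 ± 0.16) and Pdpn (0.84 ± 0.14). Smooth muscle markers rose in 11 of 17 and fell in 0 (mean 0.42 ± 0.19, adjusted p = 1.75e-06), 14 adjusted over the list alone. Members included Hspb6 at 0.94 ± 0.16. With an estimated correlation adjusted p = 0.441 for each of these 4 lists. The beta-actin and Gapdh 3' to 5' ratios and the hybridization controls also differed from day 0 at this day.

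Inflammatory lists were partly higher at day 4. Acute phase genes rose in 8 of 13 (0 fell, mean 0.70 ± 0.84, adjusted p = 0.00385; adjusted p = 0.468 with an estimated correlation), 10 adjusted over the list alone, Serpina3n by 1.63 ± 0.32. Matrix proteases rose in 9 of 20 (0 fell, mean 0.68 ± 0.73, adjusted p = 0.000651; adjusted p = 0.441 with an estimated correlation), 11 adjusted over the list alone. Complement genes rose in 5 of 12 (0 fell, mean 0.48 ± 0.26, adjusted p = 0.00385; adjusted p = 0.441 with an estimated correlation), 6 adjusted over the list alone. Monocyte and macrophage markers rose in 8 of 24 (0 fell, mean 0.39 ± 0.49, adjusted p = 0.00465; adjusted p = 0.611 with an estimated correlation), 11 higher and 1 lower adjusted over the list alone. Members included the phagocyte gene Mpeg1 at 1.09 ± 0.18. The chemokine (mean 0.43, 5 higher, 2 lower, adjusted p = 0.145), cytokine (0.35, 3 higher, adjusted p = 0.275), interferon-stimulated (0.27, 7 higher, 2 lower, adjusted p = 0.325) and neutrophil (0.41, 1 higher, 1 lower, adjusted p = 0.78) lists did not pass. Their counts adjusted over the list alone were the same. Single interferon-stimulated members still rose, Iigp1 by 1.68 and Gbp2 by 1.46, as did the antimicrobial lectin genes Reg3b by 1.95 and Reg3g by 1.63. Without day 0 mouse 4 the adjusted p of Reg3g was 0.0699.

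Epithelial lists were lower at day 4. Absorptive colonocyte markers fell in 6 of 25 (0 rose, mean -0.37 ± 0.35, adjusted p = 1.07e-07; adjusted p = 0.441 with an estimated correlation), 7 adjusted over the list alone. Members included Ceacam20 at -1.29 ± 0.24 and the water channel Aqp8 at -1.12 ± 0.28. Goblet cell markers fell in 3 of 23 (0 rose, mean -0.21 ± 0.26, adjusted p = 4.6e-05; adjusted p = 0.443 with an estimated correlation), 3 adjusted over the list alone, with Spdef, a goblet cell transcription factor, at -0.69 ± 0.20 and the mucin gene Muc4 at -0.54 ± 0.13. Genes of xenobiotic metabolism rose in 3 and fell in 6 of 36 (mean -0.18 ± 0.32, adjusted p = 0.000341; adjusted p = 0.441 with an estimated correlation), the same adjusted over the list alone. Water and ion transport genes fell in 4 of 26 (0 rose, mean -0.17 ± 0.44, adjusted p = 0.00497; adjusted p = 0.441 with an estimated correlation), 4 adjusted over the list alone. Cell cycle genes rose in 1 and fell in 3 of 34 (mean -0.22 ± 0.31, adjusted p = 0.000157; adjusted p = 0.565 with an estimated correlation), the same adjusted over the list alone. Pan-epithelial genes, a list of 18 made after the data were seen and 6 of them in lists fixed beforehand, fell in 4 (0 rose, mean -0.17 ± 0.21, adjusted p = 0.000208 over 4 such lists; p = 0.183 with an estimated correlation), after a mean of 0.06 at day 2 with 0 passing. Without day 0 mouse 4 the adjusted p of Spdef was 0.0602.

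Smaller shifts at day 4 were in junction genes (mean -0.10 ± 0.40, 3 higher, 7 lower of 27, adjusted p = 0.00385; adjusted p = 0.487 with an estimated correlation), with Cldn23, a claudin of tight junctions, at -1.003 ± 0.178. Fatty acid oxidation (mean -0.10 ± 0.31, 1 higher, 2 lower of 26, adjusted p = 0.00893) and mitochondrial respiration (mean -0.05 ± 0.10, 0 higher, 5 lower of 36, adjusted p = 0.00135) shifted slightly; adjusted p = 0.565 with an estimated correlation for both. In the adipocyte list (mean -0.50 ± 0.73, 0 higher, 1 lower of 10, adjusted p = 0.0196; adjusted p = 0.514 with an estimated correlation) the member that fell was Pck1 (-0.47 ± 0.16), an enzyme of gluconeogenesis also made outside fat. Counting within lists, and adjusted over the list alone, 4 higher and 8 lower junction genes, 1 higher and 2 lower fatty acid oxidation genes, 5 lower mitochondrial and 2 lower adipocyte genes passed. Without day 0 mouse 5 adjusted p = 0.0531 for fatty acid oxidation and 0.118 for the adipocyte list, and for Pck1, whose call ended without any of 15 arrays, it was at most 0.125, without day 0 mouse 3. With the hybridization control covariate the acute phase, macrophage, complement, junction, fatty acid oxidation, mitochondrial and xenobiotic lists did not pass. The remaining 20 lists did not pass, with means between -0.22 and 0.97 and a lowest adjusted p of 0.0868. They include stem and crypt base markers (mean -0.11, 0 higher, 3 lower of 16), although Axin2 fell by 0.75 and Lgr5, a marker of intestinal stem cells, fell by 0.61 (adjusted p = 0.083 for Lgr5 without day 0 mouse 4), and enteroendocrine markers (mean 0.21, 7 higher of 18, adjusted p = 0.107). Insl5, a hormone of colonic L cells, rose by 0.56 at day 4 (adjusted p = 0.0616 without day 0 mouse 1). Mean, median and test differed in sign for the mast cell, glycolysis and prostanoid lists.

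**Figure D2:**
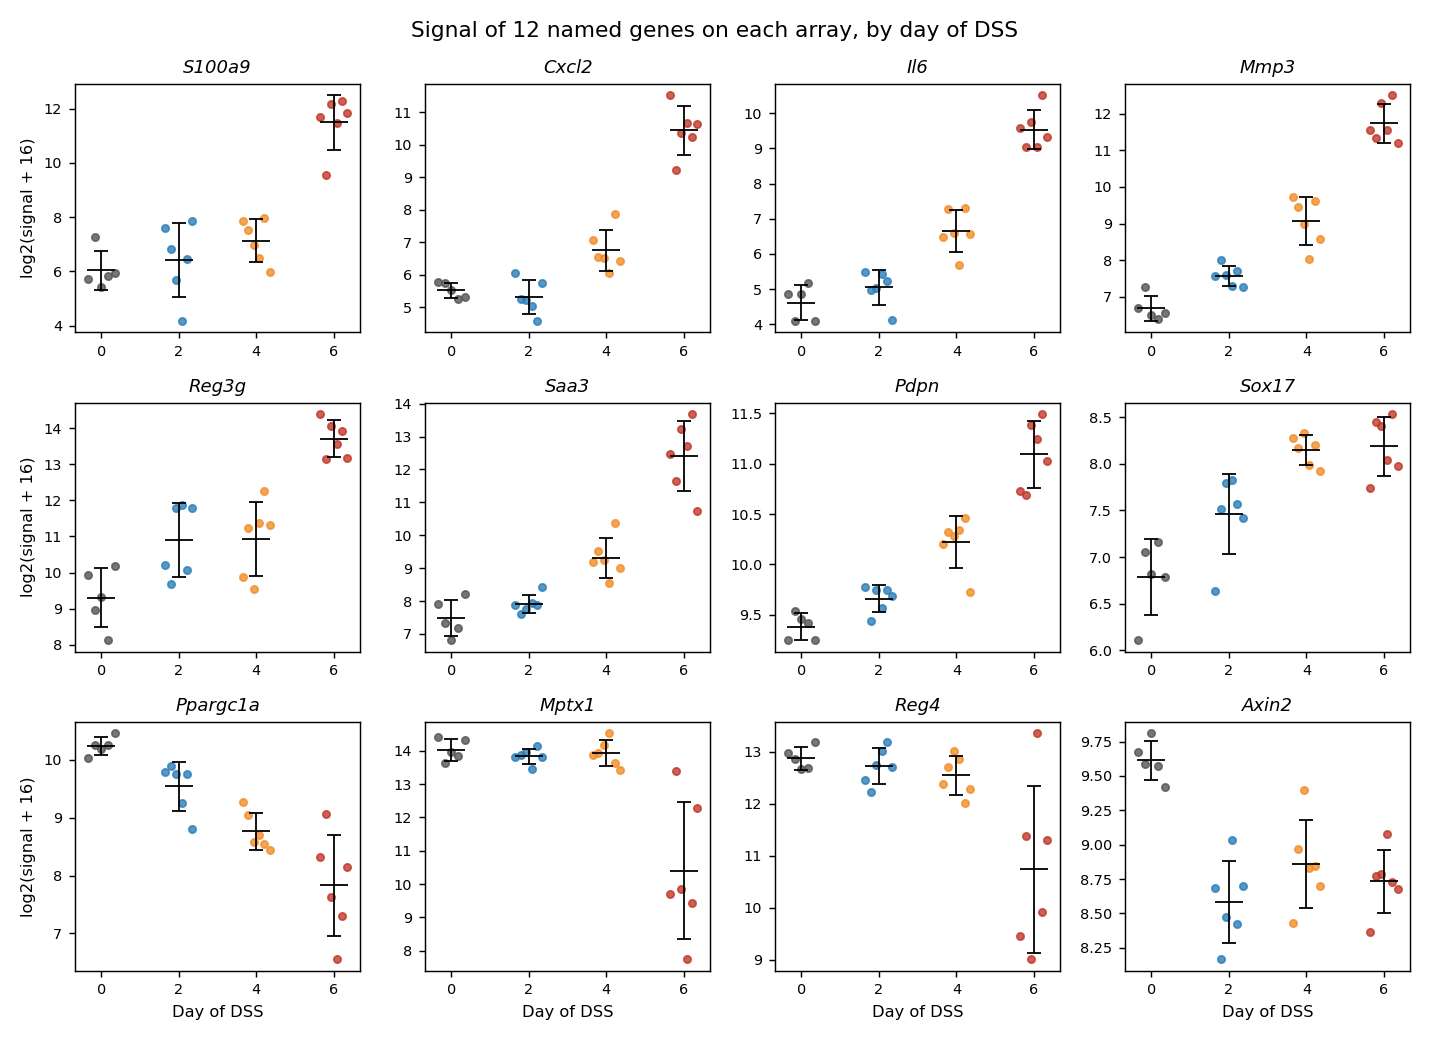
Levels of 12 genes as log2(signal + 16) on each array at days 0, 2, 4 and 6, with a point per array and the mean and SD of each day. S100a9, Cxcl2, Il6, Mmp3, Reg3g and Saa3 stand highest at day 6, Pdpn and Sox17 rise by day 4, and Ppargc1a, Mptx1 and Reg4 stand lowest at day 6.

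At day 6 genes of neutrophils, cytokines and matrix breakdown were higher than in untreated colon. S100a9, a calcium-binding protein abundant in neutrophils, rose 44.1-fold, from a mean signal of 57.7 ± 46.0 (SD, n = 5) to 3348 ± 1525 (SD, n = 6), with a log2 change of 5.46 ± 0.56 (SE, adjusted p = 1.6e-07). Its partner S100a8 rose 31.7-fold (4.99 ± 0.50), Mmp3 33.6-fold (5.07 ± 0.27, adjusted p = 1.37e-11), and the neutrophil chemokine gene Cxcl2 30.4-fold (4.93 ± 0.33, adjusted p = 4.91e-10). Mptx1, a mucosal pentraxin, fell to 0.0808 of day 0, from 17120 ± 3950 to 3067 ± 4192 (log2 change -3.63 ± 0.60, adjusted p = 6.1e-05). That fraction is of mean log levels, which ran from 7.74 to 13.41 on the day 6 arrays, and is not the ratio of the mean signals.

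Saa3 (log2 change 4.92), Il6 (4.92), Mmp10 (4.87) and the chloride channel regulator Clca4b (4.72) were the other largest increases at a pseudocount of 16. The change of Il6, near background at day 0, was 6.67 with a pseudocount of 1 and 3.44 with 64, and its rank moved with it. After Mptx1 the largest decreases were in Fut9 (-2.92), Ttr (-2.80), which encodes a thyroid hormone carrier, the transcription factor gene Etv4 (-2.45), Ppargc1a (-2.40), Nxpe2 (-2.35), 2310079G19Rik (-2.32) and the noncoding RNA Malat1 (-2.24), whose probe sets differed in sign. In total 2261 genes rose and 1783 fell (limma), 509 and 143 at least 2-fold, and 2066 genes did not overlap, where chance gives 0.433%. With the hybridization control level as a covariate 660 were higher and 561 lower, and 18 of 68 named calls were lost.

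Immune lists rose at day 6. Of 12 neutrophil markers measured, from 26 listed, 10 rose and 1 fell (mean 2.44 ± 1.77, camera adjusted p = 1.48e-06, adjusted p = 0.0547 with an estimated correlation). With the stricter filter the camera adjusted p was 0.0731. Cytokines rose in 11 of 13 (0 fell, mean 1.75 ± 1.58, adjusted p = 2.36e-07; adjusted p = 0.0464 with an estimated correlation), among them Il11 (3.78 ± 0.42) and Il1b (3.67 ± 0.33). Chemokines rose in 19 and fell in 2 of 27 (mean 1.55 ± 1.57, adjusted p = 1.85e-08; adjusted p = 0.0464 with an estimated correlation), with Cxcl9 at 4.34 ± 0.44 and Cxcl5 at 3.91 ± 0.39. Monocyte and macrophage markers rose in 22 of 24 (0 fell, mean 1.39 ± 0.96, adjusted p = 1.75e-14; adjusted p = 0.0898 with an estimated correlation), including Chil3 (4.60 ± 0.51) and the monocyte chemokine receptor gene Ccr2 (2.49 ± 0.25). Interferon-stimulated genes rose in 23 of 28 (0 fell, mean 1.17 ± 0.76, adjusted p = 9.91e-11; adjusted p = 0.16 with an estimated correlation), with Iigp1 at 3.18 ± 0.39 and Gbp2 at 2.59 ± 0.29. MHC class II genes rose in 6 of 10 (0 fell, mean 0.55 ± 0.21, adjusted p = 0.00439; adjusted p = 0.335 with an estimated correlation). When members were adjusted over the list alone, 10 neutrophil markers were higher and 1 lower, 12 cytokines higher, 20 chemokines higher and 4 lower, 22 macrophage markers higher and 1 lower, 25 interferon-stimulated genes higher and 6 MHC class II genes higher.

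Host defence and acute phase genes rose as well. Acute phase genes rose in 11 of 13 (0 fell, mean 2.28 ± 1.57, adjusted p = 3.64e-10; adjusted p = 0.0547 with an estimated correlation), 11 adjusted over the list alone. Members included the haemoglobin-binding Hp at 3.98 ± 0.65 and Serpina3n at 3.97 ± 0.32. Epithelial antimicrobial genes rose in 8 and fell in 2 of 13 (mean 0.95 ± 1.58, adjusted p = 0.00386; adjusted p = 0.114 with an estimated correlation), 9 higher and 2 lower adjusted over the list alone. Reg3g rose 21.2-fold to 14080 ± 4889 and Reg3b 9.12-fold to 24640 ± 1929 (SD, n = 6). Complement genes rose in 10 of 12 (0 fell, mean 0.98 ± 0.38, adjusted p = 3.09e-07; adjusted p = 0.0605 with an estimated correlation), 12 adjusted over the list alone. The prostanoid and leukotriene list (mean 0.29, 5 higher, 3 lower of 17, adjusted p = 0.445) did not pass, with 5 higher and 4 lower adjusted over the list alone, although Alox5ap, needed for leukotriene synthesis, rose by 1.76 and Ptgs2, an inducible cyclooxygenase, by 1.57.

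Stromal and vascular genes were higher than day 0 at day 6. All 23 matrix and fibroblast genes rose (mean 0.83 ± 0.42, adjusted p = 3.87e-13; adjusted p = 0.132 with an estimated correlation), as many adjusted over the list alone. Members included Pdpn at 1.71 ± 0.14, the collagen cross-linking enzyme Lox at 1.61 ± 0.25 and Thbs1 at 1.498 ± 0.199. Matrix proteases rose in 16 and fell in 1 of 20 (mean 1.70 ± 1.56, adjusted p = 2.11e-10; adjusted p = 0.0547 with an estimated correlation), 18 higher and 1 lower adjusted over the list alone. Members included the collagenase gene Mmp13 at 4.26 ± 0.39. Endothelial markers rose in 15 of 22 (0 fell, mean 0.70 ± 0.32, adjusted p = 1.67e-07; adjusted p = 0.158 with an estimated correlation), 21 adjusted over the list alone. Members included Sox17 at 1.41 ± 0.20. Angiogenic and endothelial activation genes rose in 10 and fell in 2 of 22 (mean 0.59 ± 0.96, adjusted p = 0.00386; adjusted p = 0.158 with an estimated correlation), the same adjusted over the list alone. Members included the leukocyte adhesion genes Selp at 3.03 ± 0.30, Vcam1 at 2.08 ± 0.20 and Icam1 at 1.70 ± 0.18. Neuron and glia markers rose in 11 of 18 (0 fell, mean 0.52 ± 0.30, adjusted p = 0.000161; adjusted p = 0.191 with an estimated correlation), 11 adjusted over the list alone. Members included the glial filament gene Gfap at 1.24 ± 0.17. Smooth muscle markers did not pass (mean -0.02, 1 higher and 1 lower of 17, the same adjusted over the list alone, adjusted p = 0.588), Hspb6 rising by 0.77 while Pln, a regulator of the muscle calcium pump, fell by 0.53. Glycolysis genes rose in 8 of 24 (0 fell, mean 0.26 ± 0.47, adjusted p = 0.0499; adjusted p = 0.465 with an estimated correlation), 8 adjusted over the list alone, and leaving out any of 11 arrays ended the call, with the highest adjusted p = 0.109 without day 6 mouse 1.

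Epithelial transport and differentiation genes fell at day 6. Goblet cell markers fell in 12 of 23 (0 rose, mean -0.55 ± 0.55, adjusted p = 4.25e-07; adjusted p = 0.163 with an estimated correlation), 15 adjusted over the list alone, with Reg4 going from 7583 ± 1187 (SD, n = 5) to 2970 ± 3806 (SD, n = 6), although day 6 mouse 7 (13.36 as log2 level) lay above every day 0 array (highest 13.19), the chloride channel gene Best2 at -1.78 ± 0.29 and Muc4 at -0.94 ± 0.13. Absorptive colonocyte markers rose in 2 and fell in 8 of 25 (mean -0.29 ± 0.63, adjusted p = 0.00439; adjusted p = 0.465 with an estimated correlation), the same adjusted over the list alone. Members included Slc37a2 at -2.11 ± 0.32 and Aqp8 at -1.23 ± 0.28. Water and ion transport genes rose in 3 and fell in 16 of 26 (mean -0.41 ± 0.69, adjusted p = 1.32e-05; adjusted p = 0.0842 with an estimated correlation), the same adjusted over the list alone. Fxyd4, a sodium pump subunit, fell by 1.68 and the potassium channel subunit gene Kcne3 fell by 1.04, while the water channel gene Aqp3 rose by 1.86. Within days 2 and 4 Aqp3 was lowest on day 2 mouse 8 and day 4 mouse 8, the arrays almost without squamous RNA, and squamous markers also rose at day 6. Tuft cell markers fell in 3 of 7 (0 rose, mean -0.53 ± 0.23, adjusted p = 0.00815; adjusted p = 0.158 with an estimated correlation), 5 adjusted over the list alone. Junction genes rose in 2 and fell in 11 of 27 (mean -0.17 ± 0.37, adjusted p = 0.0026; adjusted p = 0.297 with an estimated correlation), 2 higher and 12 lower adjusted over the list alone. Members included the tight junction genes Ocln at -0.73 ± 0.11 and Cldn23 at -0.63 ± 0.18. Pan-epithelial genes fell in 6 of 18 (0 rose, mean -0.19 ± 0.15, adjusted p = 0.00144; p = 0.238 with an estimated correlation). With the hybridization control covariate the colonocyte, junction, fatty acid oxidation and glycolysis lists did not pass.

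Metabolic lists also fell at day 6. Genes of mitochondrial respiration fell in 23 of 36 (0 rose, mean -0.18 ± 0.11, adjusted p = 4.39e-09; adjusted p = 0.164 with an estimated correlation), 26 adjusted over the list alone, with Suclg1, a subunit of a citric acid cycle enzyme, at -0.48 ± 0.06. Fatty acid oxidation genes rose in 1 and fell in 13 of 26 (mean -0.23 ± 0.54, adjusted p = 3.89e-05; adjusted p = 0.193 with an estimated correlation), 4 higher and 17 lower adjusted over the list alone. Members included the monocarboxylate transporter gene Slc16a1 at -0.49 ± 0.07. Xenobiotic metabolism genes fell in 19 of 36 (0 rose, mean -0.43 ± 0.39, adjusted p = 3.56e-08; adjusted p = 0.0898 with an estimated correlation), 20 adjusted over the list alone. Members included Cyp2f2 at -1.17 ± 0.28 and the alcohol dehydrogenase gene Adh1 at -1.07 ± 0.19.

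Squamous epithelium markers rose in 8 of 20 at day 6 (0 fell, mean 1.61 ± 0.53, adjusted p = 0.00156; adjusted p = 0.528 with an estimated correlation), 14 adjusted over the list alone. Members included Krt6b at 2.56 ± 0.78 and Krt14 at 2.33 ± 0.68. With the hybridization control covariate the list mean was -0.04 (adjusted p = 0.864). The list had not passed at day 4 (mean 0.64 ± 0.55, 0 of 20, camera adjusted p = 0.442), a day that holds mouse 8, almost without squamous RNA. On the other day 4 arrays Krt10, chosen after its values were seen, was at least 7014, against at most 4182 at day 0. Skeletal muscle genes, chosen in the same way, separated alike on these arrays. Acta1 was at least 7540 against at most 6504 at day 0, Myh1 5994 against 4005 and Ckm 3807 against 2871. At day 6 skeletal muscle markers (mean 0.85, 0 higher and 0 lower of 15, adjusted p = 0.483) and pancreatic markers (mean 0.45, 0 higher, 1 lower of 5, adjusted p = 0.912), which also come from neighbouring tissue, did not pass.

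Other lists did not pass at day 6. Stem and crypt base markers (mean -0.27 ± 0.59, 4 higher and 8 lower of 16, as many adjusted over the list alone, adjusted p = 0.056) included Ascl2, a transcription factor of crypt stem cells, at -1.20 ± 0.25 and Lgr5 at -0.97 ± 0.19. In the cell cycle list (mean 0.19, 6 higher, 0 lower of 34, adjusted p = 0.123) Rrm2, a subunit of ribonucleotide reductase, rose by 0.95 ± 0.22. The mast cell list (mean 0.70, 2 higher, 1 lower of 5, adjusted p = 0.439) held Hdc, the histamine-forming enzyme also made by other myeloid cells, at 2.74 ± 0.34, and Kit, a receptor that pacemaker cells of the gut also carry, at -0.59 ± 0.12. Thy1, which fibroblasts and neurons also make, rose by 1.19 ± 0.16 as 1 of 6 T cell markers measured, from 25 listed (mean 0.49, adjusted p = 0.191). B cell and plasma cell markers (mean 0.29, 2 higher, 1 lower of 16, adjusted p = 0.535) included Jchain at -0.55 ± 0.16. The unfolded protein response (mean 0.16, 5 higher, 2 lower of 23, adjusted p = 0.191), small intestinal (mean 0.11, 3 higher of 8, adjusted p = 0.296), adipocyte (mean 0.13, 1 higher, 1 lower of 10, adjusted p = 0.919) and enteroendocrine lists (mean 0.04, 0 of 18, adjusted p = 0.919) did not pass. By p-values adjusted over the list alone, the counts higher and lower were 4 and 0 for cell cycle, 3 and 1 for mast cells, 1 and 0 for T cells, 1 and 1 for B cells, 6 and 2 for the unfolded protein response, 3 and 1 for the small intestine and 1 and 1 for adipocytes. For pancreatic markers the mean, median and test differed in sign.

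**Figure D3:**
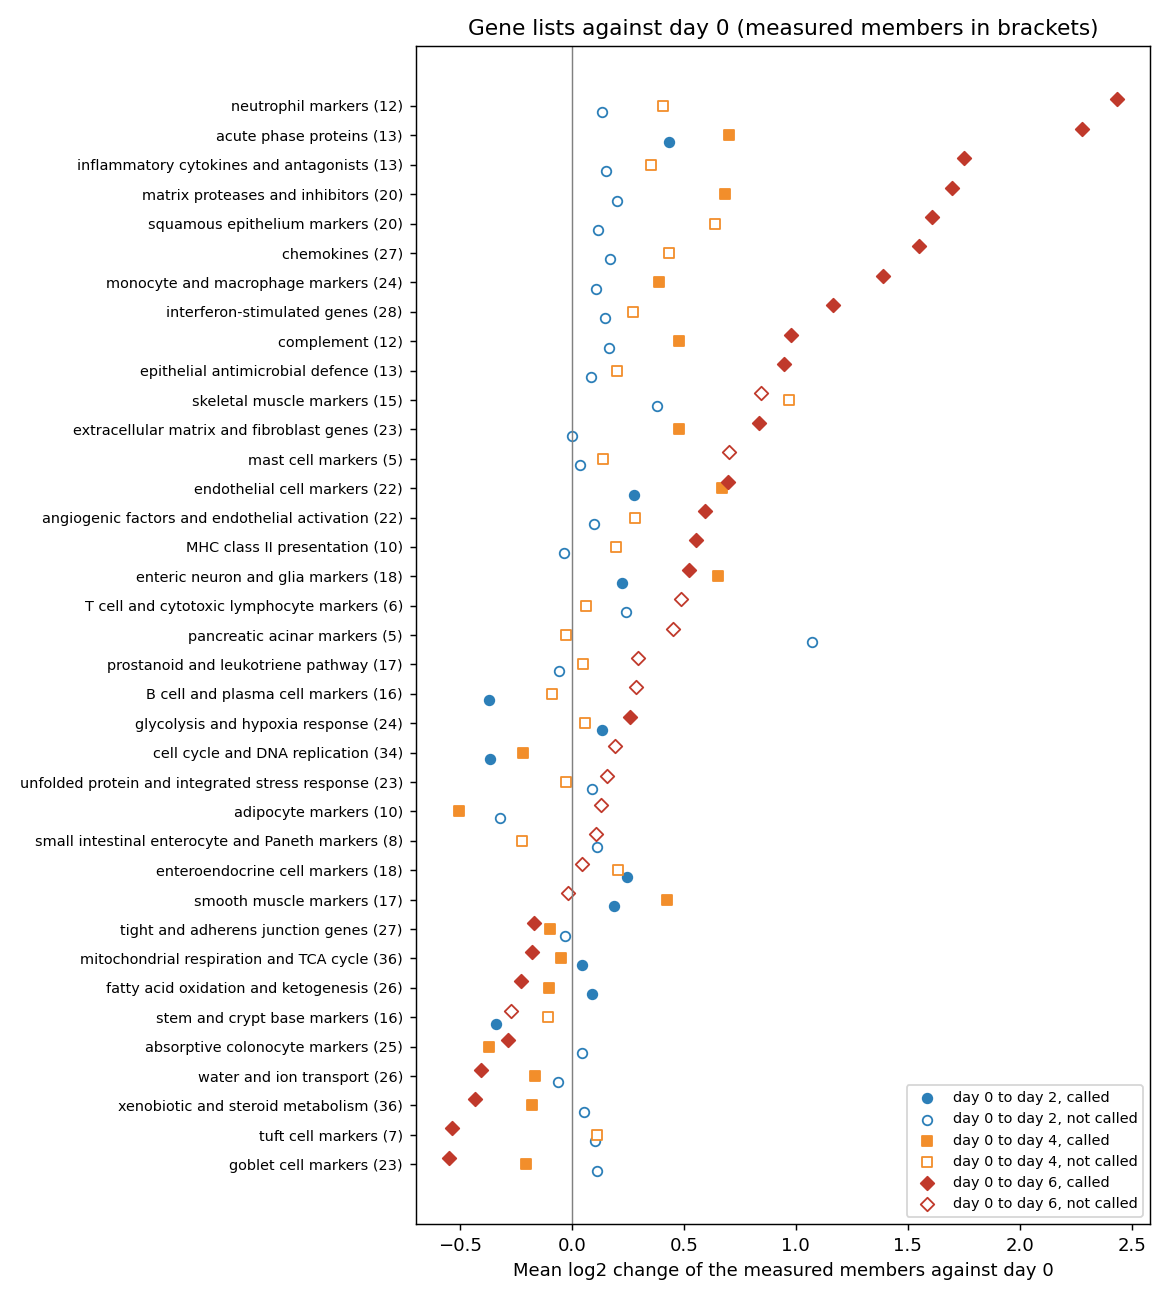
Mean log2 change of the measured members of each of the 37 gene lists against day 0, as blue circles for day 2, orange squares for day 4 and red diamonds for day 6. Filled symbols mark lists that passed the camera test, 11 at day 2, 17 at day 4 and 24 at day 6.

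Between days 2 and 4 matrix genes and Il6 rose and epithelial genes fell. Il6 rose 3.04-fold (log2 change 1.60 ± 0.31, SE, adjusted p = 0.004, log2 change 2.46 with a pseudocount of 1 and 0.88 with 64), from a mean signal of 18.6 ± 10.02 to 91.8 ± 41.6 (SD, n = 6 each), and Mmp3 2.83-fold (1.502 ± 0.257, adjusted p = 0.00198). Saa3 rose by 1.40, AB124611 by 1.35 and the interferon-induced GTPase gene Gbp6 by 1.33. Cnnm4, a magnesium transporter, fell to 0.5 of its day 2 level (-1.001 ± 0.165, adjusted p = 0.00149), and Mogat2, an enzyme of triglyceride synthesis, fell by 0.97, the carboxylesterase gene Ces2a fell by 0.89, the clock gene Nr1d1 fell by 0.87 and 5430427M07Rik fell by 0.84. In total 1175 genes rose and 510 fell (limma), 24 and 15 at least 2-fold, and 659 genes did not overlap, with chance at 0.216%. Median centring gave 818 higher and 592 lower, and the hybridization control covariate 56 and 16. None of the 29 named calls passed with that covariate, each keeping its direction, and 27 were lost under at least 1 setting fixed in advance, 13 when the mouse number block is not counted. The counts fell to 749 and 235 without day 2 mouse 17, 702 and 230 without day 4 mouse 1, 676 and 236 without day 4 mouse 3 and 526 and 188 without day 4 mouse 4, and 301 were lower without day 2 mouse 7. The change of Cnnm4 was -0.36 (adjusted p = 0.0589) with the mean of its probe sets.

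Stromal lists rose and epithelial ones fell from day 2 to day 4. Pan-epithelial genes fell in 9 of 18 (0 rose, mean -0.22 ± 0.15, adjusted p = 3.21e-09; p = 0.0494 with an estimated correlation). Matrix and fibroblast genes rose in 18 of 23 (0 fell, mean 0.48 ± 0.16, adjusted p = 4.19e-11; adjusted p = 0.348 with an estimated correlation), 21 adjusted over the list alone. Members included Lum at 0.79 ± 0.15. Neuron and glia markers rose in 10 of 18 (0 fell, mean 0.43 ± 0.21, adjusted p = 2.57e-05; adjusted p = 0.348 with an estimated correlation), 11 adjusted over the list alone. Members included Stmn2 at 0.62 ± 0.13. Endothelial markers rose in 7 of 22 (0 fell, mean 0.40 ± 0.22, adjusted p = 0.000207; adjusted p = 0.471 with an estimated correlation), 9 adjusted over the list alone. Members included Mmrn2 at 0.75 ± 0.15. Matrix proteases rose in 4 of 20 (0 fell, mean 0.48 ± 0.54, adjusted p = 0.00769; adjusted p = 0.471 with an estimated correlation), 5 adjusted over the list alone. Smooth muscle markers rose in 4 of 17 (0 fell, mean 0.24 ± 0.20, adjusted p = 0.0157; adjusted p = 0.695 with an estimated correlation), 5 adjusted over the list alone, and without day 4 mouse 4 adjusted p = 0.0676.

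Colonocyte markers fell in 12 of 25 from day 2 to day 4 (0 rose, mean -0.42 ± 0.26, adjusted p = 8.83e-12; adjusted p = 0.348 with an estimated correlation), 19 adjusted over the list alone. Goblet cell markers fell in 7 of 23 (0 rose, mean -0.32 ± 0.21, adjusted p = 7.51e-10; adjusted p = 0.348 with an estimated correlation), 16 adjusted over the list alone. The xenobiotic list (mean -0.24 ± 0.36, 3 higher, 9 lower of 36, adjusted p = 3.12e-06) and the fatty acid oxidation list (mean -0.19 ± 0.19, 0 higher, 5 lower of 26, adjusted p = 1.14e-07) fell, each with adjusted p = 0.348 with an estimated correlation. Mitochondrial respiration (mean -0.10 ± 0.10, 0 higher, 7 lower of 36, adjusted p = 2.99e-08) and the unfolded protein response (mean -0.12 ± 0.14, 0 higher, 2 lower of 23, adjusted p = 0.00048) fell with adjusted p = 0.414 with an estimated correlation. Junction genes (mean -0.07 ± 0.30, 0 higher, 5 lower of 27, adjusted p = 0.00236), glycolysis genes (mean -0.08 ± 0.28, 1 higher, 2 lower of 24, adjusted p = 0.0141) and water and ion transport genes (mean -0.10 ± 0.34, 1 higher, 1 lower of 26, adjusted p = 0.0489) shifted less; adjusted p = 0.471 with an estimated correlation for these. Counting within lists, and adjusted over the list alone, the counts higher and lower were 3 and 11 for xenobiotic, 0 and 9 for fatty acid oxidation, 0 and 15 for mitochondrial, 0 and 1 for unfolded protein response, 1 and 5 for junction, 1 and 3 for glycolysis and 0 and 1 for transport genes. Without day 2 mouse 6 adjusted p = 0.0952 for glycolysis, and for transport, lost without any of 7 arrays, it was at most 0.102, without day 4 mouse 4. Mean, median and test differed in sign for the antimicrobial, mast cell and tuft cell lists, which did not pass.

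From day 4 to day 6 inflammatory genes rose steeply. Hp rose 28.9-fold (log2 change 4.86 ± 0.62, SE, adjusted p = 1.19e-05), from a mean signal of 56.1 ± 37.1 to 2266 ± 1671 (SD, n = 6 each), S100a9 rose 20.7-fold (4.37 ± 0.53), S100a8 18.3-fold (4.19 ± 0.48), Cxcl2 12.9-fold (3.69 ± 0.32) and Chil3 11.8-fold (3.56 ± 0.49). Mptx1 fell to 0.0871 of its day 4 level (-3.52 ± 0.57), AI854703 fell by 2.45, the cytochrome P450 gene Cyp2c68 fell by 2.41, Ttr fell by 2.33 and 5033404E19Rik fell by 2.26. In total 1133 genes rose and 1712 fell (limma), 228 and 104 at least 2-fold, and 951 genes did not overlap, with chance at 0.216%. The hybridization control covariate gave 1000 higher and 1534 lower, 2354 of them among the 2845, and 1 of 53 named calls was lost.

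Immune and defence lists rose from day 4 to day 6. Neutrophil markers rose in 9 and fell in 1 of 12 (mean 2.03 ± 1.38, adjusted p = 3.29e-09; adjusted p = 0.0176 with an estimated correlation), cytokines rose in 9 of 13 (0 fell, mean 1.40 ± 1.19, adjusted p = 3.67e-09; adjusted p = 0.0147 with an estimated correlation), and chemokines rose in 16 and fell in 1 of 27 (mean 1.11 ± 1.16, adjusted p = 1.06e-10; adjusted p = 0.0147 with an estimated correlation). Acute phase genes rose in 10 of 13 (0 fell, mean 1.58 ± 1.35, adjusted p = 1.06e-10; adjusted p = 0.0361 with an estimated correlation). Il1b rose by 3.29 ± 0.32 and Cxcl5 by 3.24 ± 0.37. Macrophage markers rose in 21 of 24 (0 fell, mean 1.002 ± 0.718, adjusted p = 6.86e-16; adjusted p = 0.0821 with an estimated correlation), and interferon-stimulated genes in 21 of 28 (0 fell, mean 0.89 ± 0.46, adjusted p = 5.38e-14; adjusted p = 0.119 with an estimated correlation), with the antiviral gene Oas3 at 2.13 ± 0.44. Antimicrobial genes rose in 8 and fell in 1 of 13 (mean 0.75 ± 0.83, adjusted p = 0.000184; adjusted p = 0.0525 with an estimated correlation), complement genes rose in 6 of 12 (0 fell, mean 0.50 ± 0.35, adjusted p = 5.91e-05; adjusted p = 0.119 with an estimated correlation) and MHC class II genes in 1 of 10 (0 fell, mean 0.36 ± 0.14, adjusted p = 0.00599; adjusted p = 0.358 with an estimated correlation). Adjusted over the list alone the counts higher and lower were 10 and 1 for neutrophil, 10 and 1 for cytokine, 17 and 1 for chemokine, 12 and 0 for acute phase, 22 and 0 for macrophage, 25 and 0 for interferon, 8 and 1 for antimicrobial, 8 and 0 for complement and 0 and 0 for MHC class II genes.

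Proliferation, matrix and stress lists rose from day 4 to day 6 as well. Cell cycle genes rose in 12 of 34 (0 fell, mean 0.41 ± 0.23, adjusted p = 2.77e-08; adjusted p = 0.275 with an estimated correlation), 16 adjusted over the list alone. Members included Rrm2 at 1.002 ± 0.205 and the mitotic kinase gene Plk1 at 0.86 ± 0.22. Matrix proteases rose in 13 and fell in 1 of 20 (mean 1.01 ± 1.06, adjusted p = 7.2e-09; adjusted p = 0.0772 with an estimated correlation), 14 and 1 adjusted over the list alone. Matrix and fibroblast genes rose in 11 of 23 (0 fell, mean 0.36 ± 0.36, adjusted p = 4.46e-06; adjusted p = 0.325 with an estimated correlation), 11 adjusted over the list alone. The unfolded protein response (mean 0.18 ± 0.23, 7 higher, 1 lower of 23, adjusted p = 0.00139), glycolysis (mean 0.20 ± 0.34, 5 higher, 1 lower of 24, adjusted p = 0.00261) and angiogenic lists (mean 0.31 ± 0.67, 7 higher, 3 lower of 22, adjusted p = 0.0242) rose, each with adjusted p = 0.275 with an estimated correlation. Their counts adjusted over the list alone were 10 and 1, 7 and 1, and 8 and 4. Small intestinal markers rose in 3 of 8 (0 fell, mean 0.33 ± 0.28, adjusted p = 0.0113; adjusted p = 0.119 with an estimated correlation), 3 adjusted over the list alone. The risers were Ada, of purine breakdown, at 0.49 ± 0.13, the lysozyme gene Lyz1 at 0.48 ± 0.14 and the aminopeptidase gene Enpep at 0.32 ± 0.09, none of them made by the small intestine alone.

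Other lists that passed from day 4 to day 6 were squamous markers (mean 0.97 ± 0.61, 1 higher of 20, adjusted p = 0.00233; adjusted p = 0.5 with an estimated correlation), B cell markers (mean 0.38 ± 0.32, 0 of 16, adjusted p = 0.0242; adjusted p = 0.5 with an estimated correlation) and adipocyte markers (mean 0.63 ± 0.87, 1 higher, 1 lower of 10, adjusted p = 0.0383; adjusted p = 0.389 with an estimated correlation). Adjusted over the list alone 0 squamous and 0 B cell markers and 7 higher and 1 lower adipocyte markers passed. These calls ended when a single array was left out, with adjusted p = 0.167 for the squamous list without day 4 mouse 8, an array almost without squamous RNA, 0.161 for B cell markers without day 6 mouse 29, and 0.0883 for adipocyte markers and 0.0621 for angiogenic genes without day 6 mouse 21. These are the highest values, as leaving out any of 4 arrays ended the B cell call and any of 7 the adipocyte call. Krt6b rose by 2.05 ± 0.75 (adjusted p = 0.128 without day 4 mouse 8, the highest of 18 arrays that ended the call).

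Smooth muscle and epithelial genes fell from day 4 to day 6. Smooth muscle markers fell in 12 of 17 (0 rose, mean -0.44 ± 0.31, adjusted p = 7.38e-07; adjusted p = 0.275 with an estimated correlation), 14 adjusted over the list alone, Pln going from a mean signal of 942 ± 172 to 452 ± 78.7 (SD, n = 6 each). Tuft cell markers fell in 5 of 7 (0 rose, mean -0.65 ± 0.25, adjusted p = 0.00104; adjusted p = 0.0821 with an estimated correlation), 6 adjusted over the list alone. Members included the tuft cell transcription factor gene Pou2f3 at -1.19 ± 0.35. Water and ion transport genes rose in 1 and fell in 13 of 26 (mean -0.24 ± 0.51, adjusted p = 0.00471) and xenobiotic genes rose in 1 and fell in 13 of 36 (mean -0.25 ± 0.45, adjusted p = 0.000706), each with adjusted p = 0.275 with an estimated correlation. Goblet cell markers fell in 7 of 23 (0 rose, mean -0.34 ± 0.51, adjusted p = 0.0104; adjusted p = 0.439 with an estimated correlation), mitochondrial genes in 13 of 36 (0 rose, mean -0.13 ± 0.10, adjusted p = 2.19e-05; adjusted p = 0.325 with an estimated correlation) and fatty acid oxidation genes in 8 of 26 (0 rose, mean -0.13 ± 0.34, adjusted p = 0.00599; adjusted p = 0.38 with an estimated correlation). Adjusted over the list alone the counts higher and lower were 3 and 14 for transport, 1 and 14 for xenobiotic, 0 and 8 for goblet, 0 and 18 for mitochondrial and 1 and 14 for fatty acid oxidation genes. Insl5 fell by 0.90 ± 0.15 among enteroendocrine markers (0 higher, 5 lower of 18), a list that did not pass (adjusted p = 0.104). Without day 4 mouse 8 adjusted p = 0.0563 for the goblet list, and without day 6 mouse 7 it was 0.0509 for Pou2f3. For skeletal muscle markers, which did not pass, mean, median and test differed in sign.

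Comparisons with day 0 shared genes. Days 4 and 6 shared 1240 genes, 929 higher and 311 lower, and 15 passed in opposite directions. Independent lists of these sizes would share 273 and 77.1, and unchanged groups simulated against the same day 0 arrays shared a median of 0. With no change simulated, a shared count near 0 is given in advance for every pair of days. That count therefore does not measure how far the common day 0 arrays raise the overlap of real calls. With day 0 split between the comparisons, the median was 439 (218 to 503). A split leaves each comparison only 2 or 3 day 0 arrays, which also lowers power. The fall from 1240 is therefore not the share owed to common arrays alone. The correlation of log2 changes across genes, which are not independent replicates, was 0.647 against a simulated median of 0.563 (0.126 to 0.77), and the covariance 0.113 against 0.0205. Days 2 and 4 shared 7 genes, 1 higher and 6 lower, where independent lists give 0.241 and 0.346 and simulation and split both gave a median of 0, with splits from 0 to 6. The correlation was 0.569 against a simulated median of 0.518 (0.113 to 0.793), and the covariance 0.0433 against 0.019. Days 2 and 6 shared 7, all lower, against 0.363 higher and 1.14 lower for independent lists, a simulated median of 0 and a split median of 0.5. The splits ranged from 0 to 13, which includes 7. The correlation of 0.439 lay below the simulated median of 0.557 (-0.174 to 0.813), and the covariance was 0.0529 against 0.0207. All 3 correlations lay within their simulated ranges. Axin2 and Jchain were among those lower at day 2 and at day 6. Axin2 had a log2 change of -0.88 ± 0.15 (SE) at day 6.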

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

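The tests of the clock genes and of the distal end were chosen after the results were seen, and the fits with a skeletal muscle or hybridization control covariate or without 2 arrays after the data were seen. An array stood apart from the rest of its day, by its gap to the nearest array over the range of the day, in 9 of 148 tests of lists, 30 of 428 of named genes and 0 of 16 of quality measures. Chance gives such a gap in about 1 in 20 groups, so single genes say little. Day 4 mouse 8 accounted for 7 of these, day 2 mouse 8 for 6 and day 4 mouse 4 for 4.

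Among lists, day 2 mouse 8 was lowest in neutrophil markers (gap over range 0.74) and squamous markers (0.779), and day 4 mouse 8 was lowest in squamous (0.888) and skeletal muscle markers (0.773). Day 2 mouse 6 was highest in pancreatic markers (0.946) and lowest in enteroendocrine markers (0.634) and xenobiotic genes (0.751). Day 6 mouse 1 was highest in pancreatic markers (0.664), and day 0 mouse 1 lowest in goblet cell markers (0.767).

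Among genes, day 4 mouse 8 was lowest in Krt6b (0.923), Krt14 (0.788), Aqp3 (0.751), Lum (0.704) and Pdpn (0.656), and day 2 mouse 8 in Cyp2f2 (0.756), Krt14 (0.751), Cyp2c68 (0.739) and Aqp3 (0.644). Day 4 mouse 4 was highest in Pln (0.719), Lgr5 (0.696) and Fut9 (0.67) and lowest in Slc37a2 (0.738). Day 6 mouse 3 was lowest in Hdc (0.719), S100a9 (0.7) and S100a8 (0.651). Day 0 mouse 2 was highest in S100a9 (0.738) and lowest in Cxcl9 (0.756) and Kcne3 (0.735). Day 0 mouse 5 was highest in Hp (0.831) and 5430427M07Rik (0.782), while day 0 mouse 1 was highest in Il1b (0.754) and lowest in Ocln (0.745). Day 6 mouse 4 was highest in Oas3 (0.687) and lowest in 5430427M07Rik (0.661), and day 6 mouse 29 was highest in Aqp3 (0.641). The others were Sox17 on day 2 mouse 1 (0.661), Il6 on day 2 mouse 52 (0.636), Icam1 on day 2 mouse 7 (0.629) and Mogat2 on day 4 mouse 6 (0.629), each lowest.

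Some results moved apart between days by a test of the difference itself. Fatty acid oxidation genes, slightly higher at day 2, differed by -0.19 between days 4 and 2 (adjusted p = 1.14e-07; adjusted p = 0.348 with an estimated correlation) and by -0.32 between days 6 and 2 (adjusted p = 1.33e-09; adjusted p = 0.0745 with an estimated correlation). Mitochondrial respiration genes differed by -0.10 (adjusted p = 2.99e-08; adjusted p = 0.414 with an estimated correlation) and -0.22 (adjusted p = 1.08e-13; adjusted p = 0.0755 with an estimated correlation) in the same comparisons. Both lists lay below the day 2 mean on 6 of 6 arrays of either later day. None of these list differences held with an estimated correlation. Pln, higher than day 0 at day 4 and lower at day 6, differed by -1.03 between them (adjusted p = 1.27e-05), with 6 of 6 day 6 arrays below every day 4 array.

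Probe sets without a single gene symbol, which the comparisons of genes leave out, also changed. Of 2986 tested with limma, 6 were higher than day 0 at day 2, 178 at day 4 and 326 at day 6, and 8, 187 and 273 were lower.

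Clock genes were shifted at days 2 and 4. The lists were made after Dbp and Clock had been seen among the day 2 calls and hold both, so the day 2 test in part restates those calls. Genes that peak with Dbp (10 genes) had a mean log2 change of 0.82 at day 2 (adjusted p = 6.73e-10, p = 0.00819 with an estimated correlation) and 0.53 at day 4 (adjusted p = 0.0338, p = 0.315 with an estimated correlation), with 1 and 4 members higher and 0 lower. Nr1d1 (-0.33) and Per1 (-0.23) went the other way at day 4 without passing. Those that peak with Arntl (5 genes) had -0.68 (adjusted p = 3.42e-08, p = 0.000251 with an estimated correlation) and -0.49 (adjusted p = 0.000776, p = 0.0108 with an estimated correlation), with 1 and 2 members lower and 0 higher. Each list moved this way against the day 0 mean on 6 of 6 arrays of either day. For the Dbp and Arntl lists, 5 and 6 day 2 arrays lay beyond every day 0 array, but only 3 and 3 day 4 arrays did. The levels also varied within a day. As log2 deviations from all arrays, untreated day 0 mouse 4 had 0.382 and -0.127. The other day 0 arrays had -0.597 to -0.244 and 0.266 to 0.493. Dbp list levels were negative on day 4 mice 1, 3 and 4 and positive on mice 6, 7 and 8. Within days the 2 levels went opposite ways across 23 arrays (Pearson r = -0.639, permutation p = 0.009, Spearman rho = -0.554, permutation p = 0.02, r = -0.497 without the 2 farthest arrays), which any change of the clock gives and which is therefore no test of the hour of collection. The difference between the lists changed from day 0 by 1.499 at day 2, 1.018 at day 4 and -0.416 at day 6, and from day 2 to day 6 by -1.915 (SE 0.297), which argues against a shift of both lists that stayed at its day 2 size. Nfil3 alone set the sign at day 6, since without it the changes were 0.143 (SE 0.283) at day 6 and -1.366 (SE 0.269) from day 2 to day 6. A different hour of collection on each day, which the sources used here do not give, and an effect of DSS on the clock cannot be told apart. At day 6 Clock (-0.37, adjusted p = 0.0026) and Npas2 (-0.60, adjusted p = 0.038) were lower than the day 0 mean on 6 and 5 of 6 arrays, and Nfil3 (2.46, adjusted p = 2.54e-05) was higher on 6 of 6. Nr1d1, of the Dbp list, was lower at day 6 (-0.53, adjusted p = 0.0483), a call that ended without any of 14 arrays.

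Squamous markers were 1.61 higher at day 6 than at day 0 on the log2 scale, with all 6 day 6 arrays above the day 0 arrays. With the skeletal muscle marker level as a covariate the mean change was 1.128 (camera adjusted p = 0.000533), so that level alone did not account for the rise. It is an imperfect proxy for anal canal tissue. On day 6 mouse 4 Acta1 was 1516, the lowest of the 19 arrays compared above, while Krt10 was 8460, over their median of 7102. More anal canal tissue is therefore not excluded. The 2 arrays almost without squamous RNA are of days 2 and 4, so they lie outside this mean difference, and the fit without them (adjusted p = 3.02e-11) is no test of it. With the hybridization control level as a covariate, a level nearly tied to day, the mean change was -0.04 (adjusted p = 0.864), and with an estimated correlation adjusted p = 0.528. More anal canal tissue, a change in the mucosa, which was not tested, and a hybridization batch that followed day all stay open.

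Posterior Hox genes were lower at day 6, with a mean log2 change of -0.74 over 7 genes (adjusted p = 0.0379, p = 0.218 with an estimated correlation), of which 3 passed. Hoxb13 fell by 2.24 ± 0.40 (SE, adjusted p = 0.000142), Hoxd13 fell by 1.37 ± 0.42 (adjusted p = 0.0136) and Hoxa13 fell by 0.85 ± 0.23 (adjusted p = 0.00586), each lower on 6 of 6 arrays than on any day 0 array, while Hoxa11 had 0.39 ± 0.18 (adjusted p = 0.104, above the day 0 mean on 5 of 6 arrays). Less of the distal end in the dissected piece predicts lower squamous markers, which instead changed by 1.609 (SE 0.743), but by -0.04 with the hybridization control covariate, so this explanation stays open. Fewer epithelial cells predicts as large a fall in pan-epithelial genes, whose median change was -0.161 (18 genes, interquartile range 0.18) against -0.452 for the Hox genes. Regulation of these genes may contribute but was not tested.

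Splits of the same arrays show how often a regrouping calls as much, by the count of 100 splits, the real one included, that do. For genes from day 0 to day 2 the real split called 10 and 2 splits as many. The highest other called 76, for a reason that was not tested, so these 10 calls are weak evidence of an effect of day even though the count is under 5 of 100. For genes in the other comparisons no other split called as many, the lowest share that 100 splits can show. Any difference that followed day, in dissected tissue or hybridization as well, would give this result. For day 4 the real count was 2043 against a highest other of 1571, for day 6 it was 4044 against 3191, from day 2 to day 4 it was 1685 against 460 and from day 4 to day 6 it was 2845 against 1080, each with 1 split. For lists chance was not excluded. At day 2 the real split called 11 and 29 splits as many (highest other 17), at day 4 it called 17 and 20 splits as many (21), and at day 6 it called 24 and 7 splits as many (26). From day 2 to day 4 it called 14 and 37 splits as many (23), and from day 4 to day 6 it called 26 and 5 splits as many (29).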

How the results depend on the processing

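Tests without the pancreatic arrays or those low in squamous and skeletal muscle RNA, and with a squamous, skeletal muscle or hybridization control covariate, were chosen after seeing the data. Across settings, values of lists kept their side of the threshold in 7812 cases, became stronger in 210, weaker in 260 and reversed in 8. Those of named genes did so in 21441, 186, 693 and 0. A change of sign was counted as reversed only where the main fit or the setting passed. Changes of sign where neither passed are among the cases that kept their side. Of 92 list calls, 6 held with an estimated correlation, 63 with fry, 75 with fry's mixed test, 77 with the hybridization control covariate and 75 with a mouse number block. Of the named genes called, a planned setting ended 10 of 10 at day 2, 7 of 41 at day 4, 4 of 68 at day 6, 27 of 29 from day 2 to day 4 and 7 of 53 from day 4 to day 6. These counts leave aside fits without single arrays. Planned settings other than the mouse number block, which does not pair the arrays, ended 8, 3, 3, 13 and 4 in that order. A setting chosen after seeing the data ended 7 of 10, 29 of 41, 18 of 68, 29 of 29 and 1 of 53 in the same order. The causes were not tested.

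Mouse numbers do not pair the arrays: of 17 pairs with 1 number, 3 correlated above 0.1 (-0.157 to 0.703, median 0.045). With a mouse number block, calls at day 2 fell to 0 higher and 0 lower, at day 6 to 1431 and 1018, and from day 2 to day 4 to 63 and 24. Colonocyte (-0.27) and unfolded protein response genes (-0.091) reversed at day 2, and transport genes (0.015) from day 2 to day 4.

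The day 2 counts, 2 higher and 8 lower in the main setting, were 1 higher with no filter, 14 lower with the stricter filter, 4 higher with quantile normalization or median centring, 1 and 3 without the trend, 34 and 26 with only these 2 groups and 53 and 82 with array weights. They were 1 and 4 for mice 1 to 8, without the pancreatic arrays or without the arrays low in squamous RNA, 1 and 2 without all 4, 5 higher with the squamous covariate and 1 higher with the hybridization covariate. Lists called were 0 with an estimated correlation, 2 with fry and 1 with fry's mixed test.

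At day 4 the mean of probe sets gave 1201 higher and 952 lower, and the hybridization covariate gave 264 and 68. The mean of probe sets turned the sign of 133 of 2043 calls at day 4 and 84 of 4044 at day 6. It turned 97 of 1685 from day 2 to day 4 and 42 of 2845 from day 4 to day 6. At day 6, with 2261 higher and 1783 lower in the main setting, the stricter filter gave 1358 and 1519, the mean of probe sets 2062 and 2063, and the hybridization covariate gave 660 and 561. From day 2 to day 4, mice 1 to 8 gave 622 and 175 and the hybridization covariate 56 and 16. With an estimated correlation lists called were 0 at day 4, 2 at day 6, 0 from day 2 to day 4 and 4 from day 4 to day 6. With the hybridization covariate squamous markers reversed at day 4 (-0.59), day 6 (-0.044) and from day 2 to day 4 (-0.53), as did skeletal muscle markers from day 2 to day 4 (-0.85). These reversed at day 6 with the squamous covariate (-1.07). Splitting day 0, which leaves fewer day 0 arrays in each comparison, lowered the shared genes to 0 for days 2 and 4, 0.5 for days 2 and 6 and 439 for days 4 and 6.

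Leaving out 1 array gave 1 to 9 higher, 3 to 23 lower and 9 to 17 lists at day 2, 1094 to 1592, 371 to 572 and 16 to 22 at day 4, and 1993 to 2383, 1491 to 1823 and 23 to 26 at day 6. It gave 526 to 1247, 188 to 607 and 12 to 18 from day 2 to day 4, and 919 to 1224, 1425 to 1832 and 22 to 27 from day 4 to day 6. Genes with signals near background, such as Il6 at day 0, have folds that depend on the pseudocount.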

Other observations

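The families of genes were tested after the main results were seen, as 144 groups of at least 10 genes with a common symbol stem. At day 6 the Cxcl family was higher (12 genes, 10 higher and 0 lower, mean log2 change 2.29, adjusted p = 4.36e-08, adjusted p = 0.17 with an estimated correlation), with 11 of the 12 in lists fixed beforehand. Also higher were Col genes (27 genes, 11 of them in those lists, 14 higher and 0 lower, mean 0.48, adjusted p = 0.0019, adjusted p = 0.745 with an estimated correlation). Clec genes were higher too (14 genes, 2 of them in those lists, 7 higher and 1 lower, mean 1.06, adjusted p = 0.00681, adjusted p = 0.448 with an estimated correlation). Klhl genes were higher at day 4 (27 genes, 0 of them in those lists, 9 higher and 0 lower where 1504 of all 12464 genes were higher, mean 0.29, adjusted p = 0.0453, adjusted p = 0.913 with an estimated correlation). Each family stood above its level on the day 0 arrays on 6 of 6 arrays.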
